A study of Homo sapiens with 16 samples.

How the data were processed

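Whole blood of 4 volunteers was divided into aliquots and irradiated outside the body with gamma rays from a caesium source, per the labels' protocols. Each volunteer gave an aliquot at each of 4 doses, 0.0, 0.3, 1.5 and 3.0 Gy, so that the 16 arrays form 4 groups of 4. The exposures lasted 0, 3, 16 and 32 s. Blood stayed at room temperature, red cells were lysed about 30 min after irradiation, and the labels give the leukocytes as measured 1 hr after exposure. Labelled cDNA was made from 100 ng of total RNA and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols.

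The values used here are the authors' deposited log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA, oligo and limma, without versions or order, and the human genome build hg19. RMA is a procedure that corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set on the log2 scale. The other steps and settings are not given in the sources used here. The deposited log2 values ran from 2.26 to 14.6, and the medians of the 16 arrays lay between 7.65 and 7.73. No further normalisation was applied before testing. Because RMA makes arrays alike, a change shared by most transcripts could not be seen in these values. Pairs of arrays correlated with r between 0.987 and 0.997 and 0 pairs were identical. The number of arrays limits the precision of every value.

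Probe sets were named through the platform annotation. Of 33297 probe sets, 19460 carried 1 gene symbol, 1754 carried several and 12083 carried none. The 21214 probe sets with at least 1 symbol were tested, without a filter on dim signals. No gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 19429 had a gene identifier found in the RefSeq gene table for GRCh38, and 0 symbols changed when updated through it. No coordinates are given because that table is for another genome build than hg19. The single symbols named 18417 distinct genes, and 769 of them had several probe sets, of which the one with the highest mean over all arrays stood for the gene. Among the tested probe sets, 403 repeated the values of another one.

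Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with dose group and volunteer as terms and all 16 arrays in 1 fit, which left 9 residual degrees of freedom. The same model with dose in Gy as a number gave a slope per Gy with 11 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and 0.05 was the threshold. Errors are given as the standard error (SE) of the fit or as the standard deviation (SD) of the 4 differences within volunteers. The volunteers are separate donors, and the volunteer term removes differences in level between them. The p-values therefore measure how far the dose changes vary between donors, together with the spread between handled aliquots and arrays.

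The volunteer term was used because the series description states that every volunteer was measured at every dose. The pairing showed in the values. Deviations from the dose means correlated with r between 0.27 and 0.71 for arrays of the same volunteer and between -0.47 and 0.068 for arrays of different volunteers. For 16 of 16 arrays the most correlated array of another dose came from the same volunteer.

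The design, the tests, 23 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were p53 targets, genes often proposed as radiation markers (of which H2AX and CDKN1A were measured), immediate early genes, NF-kB and inflammatory cytokines, interferon response, heat shock and chaperones, oxidative stress and hypoxia, DNA damage sensing and repair, apoptosis regulators, cell cycle and proliferation, markers of T cells, B cells, NK cells, monocytes, neutrophils, eosinophils and basophils, red cells and reticulocytes, and platelets, and the zinc finger genes, small nucleolar RNAs, replication-dependent histones, olfactory receptors and ribosomal proteins. Each list was tested with limma's camera (preset inter-gene correlation 0.01) against the other probe sets, with Benjamini-Hochberg adjustment over the 23 lists of a comparison. Camera with an estimated correlation and fry were run beside it. For the slopes, the list means were also tested with an exact permutation test over all 331776 reassignments of doses within volunteers. Counts of list members past 0.05 were taken over all probe sets and again adjusted over the list alone. The adjustment over the list alone was made within each list, without a correction across the 23 lists.

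The rule named, for each dose against 0.0 Gy and for the dose slope, up to 12 genes per direction past the threshold with the same direction in all 4 volunteers, or the 5 genes with the smallest p where none passed. It also named up to 4 members per list with the smallest p at 3.0 Gy, and always CDKN1A, MDM2, H2AX, GADD45A and DDB2, with FDXR, which is not analysed here, and a further gene that is not reported here. Genes on the Y chromosome and XIST were never named.

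The procedure was tested on simulated data made from the spread of the 21214 probe sets with 200 changed ones. At a simulated log2 change of 0.3 at 3.0 Gy, 36.1% of the changed probe sets were recovered by the comparison of 3.0 with 0.0 Gy and 56.0% by the slope. At a change of 0.5 these shares were 87.1% and 92.5%, and at a change of 1 they were 99.6% and 100%. False calls averaged between 2.4 and 13.6 per run. The simulated changes were exactly linear in dose, which favours the slope. The noise was drawn independently for each probe set, without variation shared by genes, so these rates may not hold for the real arrays.

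Alternatives were a fit without the volunteer, the volunteer as a random effect, quantile normalization, centring on array medians, leaving out the dimmest 33% of probe sets, testing all probe sets, an intensity trend with a robust prior, fits on the 2 groups compared, dose rank in place of dose, leaving out each volunteer, an estimated inter-gene correlation, and all probe sets of list members. Counting identical probe sets once, the platelet marker mean as a covariate, and leaving out the 3.0 Gy array of volunteer 1 or the 0.0 Gy array of volunteer 3 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.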

Results

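Leukocyte transcripts were measured 1 hr after gamma irradiation of whole blood to show which genes change soon after exposure and whether the changes follow the dose. Each of 4 volunteers contributed 1 array at 0.0, 0.3, 1.5 and 3.0 Gy, and the 0.0 Gy aliquot served as that volunteer's control. The array medians lay between 7.65 and 7.73 on the log2 scale. The 3.0 Gy array of volunteer 1 had the lowest mean correlation with the other arrays (r = 0.990). Changes are given as log2 differences from 0.0 Gy within volunteers, as means with n = 4.

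At 3.0 Gy, the highest dose, several stress and activation genes stood above their 0.0 Gy level. PCNA, the sliding clamp of DNA replication and repair, was at 1.32 times its control level (log2 change 0.40 ± 0.20 SD). JUN, a subunit of the AP-1 transcription factor, had a log2 change of 0.37 ± 0.19 SD, and CD69, an early activation marker of lymphocytes, one of 0.30 ± 0.087 SD. The cytokine OSM had a log2 change of -0.51 ± 0.32 SD, the transcription factor EGR3 one of -0.60 ± 0.38 SD, G0S2, an inhibitor of lipolysis, one of -0.55 ± 0.43 SD, and the chemokine CXCL8 one of -0.31 ± 0.17 SD. Each of these genes moved the same way in 4 of 4 volunteers. For OSM the change was -0.99 in volunteer 1 and -0.37 to -0.33 in the others. For G0S2 it was -1.18 in volunteer 1, and the mean was -0.34 without that volunteer, and for EGR3 it was -1.15, with a mean of -0.42 without that volunteer.

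None of these changes passed over all genes. With limma, 0 of 21214 probe sets passed an adjusted p of 0.05 between 3.0 and 0.0 Gy, and 772 had an unadjusted p under 0.05, where 1060.7 are expected by chance. The smallest adjusted p was 0.196 (limma, Benjamini-Hochberg), shared by OSM, CD69, PCNA and the histone gene H2BC21 (log2 change -0.33 ± 0.057 SD). An intensity trend with a robust prior called 14 probe sets, 4 higher and 10 lower, among them OSM, CD69, PCNA, H2BC21 and CXCL8, and the other settings called 0. The 10 lower included several small nucleolar RNA probe sets with identical values, each with a log2 change of -0.28.

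Within the lists, 20 members passed at 3.0 Gy when adjusted over the list alone, without a correction across the 23 lists. Of 50 measured p53 targets, PCNA and PLK2 rose when adjusted over the list alone, and 0 passed over all genes. PLK2, a polo-like kinase, had a log2 change of 0.37 ± 0.27 SD, with 0.77 in volunteer 2 and 0.20 to 0.29 in the others. Of 39 immediate early genes, JUN and CD69 rose and FOSB, NR4A2 and EGR3 fell when adjusted over the list alone, and 0 passed over all genes. Of 39 NF-kB and inflammatory genes, OSM, G0S2, CXCL8 and BCL2A1, an anti-apoptotic BCL2 relative, fell when adjusted over the list alone, and 0 passed over all genes. The neutrophil markers, whose cells express many of these cytokine genes, averaged a log2 change of -0.039 ± 0.16 SD. Only JUN, CD69, EGR3, G0S2 and OSM stayed past the threshold with any 1 volunteer left out, and 15 of the 20 passed without the 3.0 Gy array of volunteer 1. PCNA and H2BC21 lost the call without volunteer 2 (limma, list adjusted p = 0.0632 and 0.0942), PLK2 without volunteer 2 (0.309), 3 (0.0652) or 4 (0.160), and CXCL8 without volunteer 3 (0.0701) or 4 (0.0544). Without the volunteer term, 2 of the 20 passed, PCNA and H2BC21.

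The genes most often proposed as radiation markers moved little by 1 hr. CDKN1A, an inhibitor of cyclin-dependent kinases, had a log2 change of 0.14 ± 0.063 SD, above 0 in 4 of 4 volunteers. It passed when adjusted over the marker list alone (limma, adjusted p = 0.0427 over the list), which held only 2 measured genes. That call ended with any volunteer left out (highest adjusted p = 0.191, limma). At 3.0 Gy CDKN1A passed neither among the 50 measured p53 targets nor over all genes (limma, adjusted p = 0.999 over all genes). H2AX, a histone variant phosphorylated at DNA breaks, had a log2 change of 0.015 (95% interval -0.11 to 0.14) in transcript level, which does not measure phosphorylation. MDM2, a ubiquitin ligase, had one of -0.0046 (-0.12 to 0.11), and DDB2, a repair factor for ultraviolet damage, one of 0.014 (-0.10 to 0.13). GADD45A had a log2 change of 0.15 (-0.0095 to 0.30), above 0 in 4 of 4 volunteers, and its interval reaches to a change of 0.30.

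Among the other lists, 5 of 177 small nucleolar RNAs (SNORD28, SNORD81, SNORD115-32, SNORA38B and SNORA75) rose when adjusted over the list alone, with log2 changes between 0.37 and 0.52. These guide chemical modification of ribosomal and other RNAs. Without volunteer 1 all 5 lost the call (limma, list adjusted p from 0.0946 to 0.128), as did FOSB, NR4A2, BCL2A1, OR8I2 and OR4M2 (from 0.0866 to 0.470). Of these 10, all but SNORD115-32 also lost it without another volunteer. Among them, OR8I2, OR4M2 and SNORD115-32 were dim, with mean log2 levels of 4.97, 6.70 and 4.37 at 0.0 Gy. The dimmest 33% of probe sets had means up to 7.22. H2BC21 fell among 63 histone genes when adjusted over the list alone. Among 341 olfactory receptors, best known for their role in smell, OR8I2 rose by 0.39 and OR4M2 fell by 0.37 when adjusted over the list alone. No member passed in this way at 3.0 Gy in the lists of interferon response (33 measured), heat shock (21), oxidative stress (28), DNA repair (52), apoptosis (28), cell cycle (38), T cell (25), B cell (18), NK cell (20), monocyte (17), neutrophil (22), eosinophil and basophil (12), red cell (14) or platelet markers (18), zinc finger genes (495) or ribosomal proteins (37).

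As whole lists, 7 lay above and 2 below the other probe sets at 3.0 Gy by camera with its preset correlation (adjusted p from 6.20e-12 to 0.0312), and 0 did with an estimated correlation. Against no change, 0 of 23 lists passed by fry. Small nucleolar RNAs averaged a log2 change of 0.077 ± 0.089 SD, platelet markers 0.080 ± 0.14 SD and B cell markers 0.046 ± 0.039 SD, each with camera adjusted p = 0.380 with an estimated correlation. Heat shock genes averaged 0.035 (adjusted p = 0.481 with an estimated correlation by camera) and p53 targets 0.027 (adjusted p = 0.615 with an estimated correlation). NF-kB and inflammatory genes averaged -0.083 ± 0.14 SD (adjusted p = 0.615 with an estimated correlation by camera). Immediate early genes averaged -0.067 ± 0.15 SD, ribosomal proteins 0.014 and olfactory receptors 0.0098, all with camera adjusted p = 0.795 with an estimated correlation. The olfactory receptors stood 0.29 above control on the 3.0 Gy array of volunteer 1, and without that volunteer the list was called in the opposite direction (mean -0.083, camera adjusted p = 4.98e-09), as it was without that array (-0.074, adjusted p = 8.14e-07). Without the 0.0 Gy array of volunteer 3 its call ended (-0.0076). With any volunteer left out, the small nucleolar RNAs alone kept the call: it ended for NF-kB genes (-0.022) and immediate early genes (-0.0058) without volunteer 1, for p53 targets (-0.011) without volunteer 2, for platelet markers (0.019) without volunteer 3, and for B cell markers (0.041) without volunteer 4. It also ended for heat shock genes without volunteer 2 (0.011) or 4 (0.026), and for ribosomal proteins without volunteer 2 (0.0064), 3 (-0.0059) or 4 (0.0090).

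**Figure D1:**
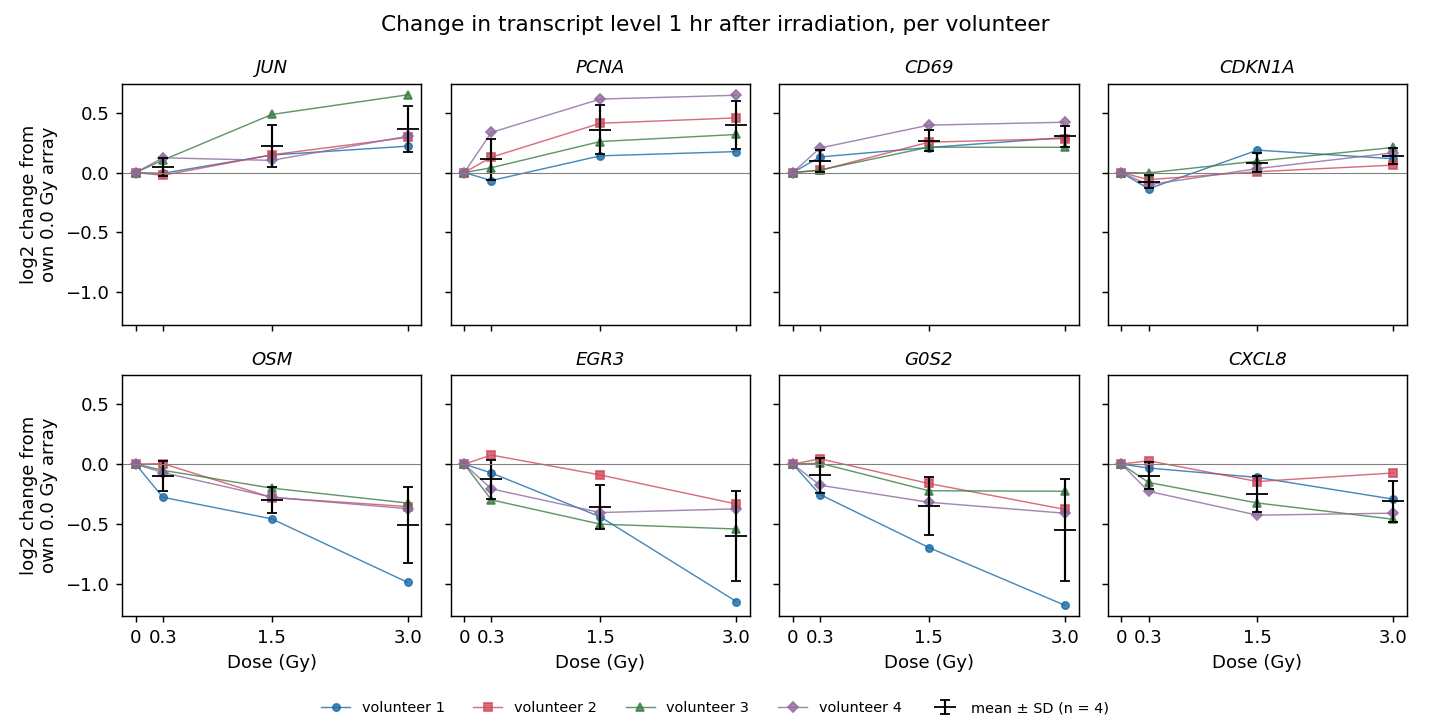
Log2 change of 8 transcripts from each volunteer's own 0.0 Gy array (vertical axis) against dose in Gy (horizontal axis). Lines join the 4 arrays of a volunteer, and black bars give the mean ± SD over 4 volunteers. JUN, PCNA, CD69 and CDKN1A lie above 0 and OSM, EGR3, G0S2 and CXCL8 below 0 in all 4 volunteers at 3.0 Gy, with mean changes from 0.14 to 0.40 and from -0.60 to -0.31.

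At 1.5 Gy, PCNA and CD69 again stood above control and OSM, CXCL8 and BCL2A1 below it. PCNA had a log2 change of 0.36 ± 0.21 SD and CD69 one of 0.27 ± 0.088 SD. MIR17HG, the host transcript of a microRNA cluster, had a log2 change of 0.39 ± 0.089 SD, and H2BC21 one of -0.28 ± 0.15 SD. OR4M2 had the smallest p, with a log2 change of -0.41 ± 0.13 SD. All of these moved the same way in 4 of 4 volunteers.

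With limma, 0 of 21214 probe sets passed an adjusted p of 0.05 between 1.5 and 0.0 Gy, and 591 had an unadjusted p under 0.05. The smallest adjusted p was 0.877 (limma, Benjamini-Hochberg), and the count was 0 in the other settings except without the 0.0 Gy array of volunteer 3, where OR4M2 was called. When adjusted over the list alone, 8 list members passed. PCNA rose among the p53 targets, CD69 among the immediate early genes and CLEC1B, a platelet receptor, among the platelet markers (log2 change 0.30 ± 0.059 SD). BCL2A1, OSM and CXCL8 fell among the NF-kB genes, with log2 changes of -0.24, -0.30 and -0.25, H2BC21 among the histones and OR4M2 among the olfactory receptors. With any 1 volunteer left out, 0 of these 8 passed throughout, and PCNA and CD69 had list adjusted p = 0.121 and 0.161 without volunteer 4 and 0.0948 and 0.0586 without volunteer 2 (limma). Without the volunteer term 1 passed, and without the 0.0 Gy array of volunteer 3 the 3 NF-kB genes were lost.

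At this dose camera placed 6 lists above and 3 below the other probe sets with the preset correlation (adjusted p from 1.65e-21 to 0.00604) and 0 with an estimated one. Against no change, 0 of 23 lists passed by fry. Small nucleolar RNAs averaged 0.10 ± 0.11 SD and B cell markers 0.067 ± 0.054 SD (both adjusted p = 0.207 with an estimated correlation, camera). Platelet markers averaged 0.088 ± 0.082 SD, with 16 of 18 members above 0 (adjusted p = 0.414 with an estimated correlation, camera). Eosinophil and basophil markers averaged -0.14 ± 0.21 SD, neutrophil markers -0.072 ± 0.11 SD, heat shock genes 0.032, ribosomal proteins 0.031 and p53 targets 0.029, all with camera adjusted p = 0.494 with an estimated correlation. NF-kB genes averaged -0.067 ± 0.084 SD (adjusted p = 0.621 with an estimated correlation, camera). The call held with any volunteer left out for small nucleolar RNAs, B cell markers and platelet markers. It ended for p53 targets without volunteer 2 (0.0010), heat shock genes without volunteer 2 (0.011) or 4 (0.00995), NF-kB genes without volunteer 1 (-0.033) or 3 (-0.075), neutrophil markers (-0.067) and eosinophil and basophil markers (-0.11) without volunteer 3, and ribosomal proteins (0.0052) without volunteer 4.

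At 0.3 Gy, the lowest dose, PCNA had a log2 change of 0.11 ± 0.17 SD, JUN one of 0.050 and OSM one of -0.099. The platelet markers averaged -0.11 ± 0.057 SD, lower in 4 of 4 volunteers and in 16 of 18 members (camera, adjusted p = 0.736 with an estimated correlation, and fry adjusted p = 0.580). The smallest p-values belonged to RBKS, a ribokinase (log2 change -0.26 ± 0.088 SD), OR8I2 (0.36 ± 0.034 SD), B4GAT1, a glycosyltransferase (-0.23 ± 0.056 SD), BCS1L, a mitochondrial chaperone (-0.22 ± 0.090 SD), and the Wnt co-receptor LRP6 (-0.20 ± 0.061 SD). Each moved the same way in 4 of 4 volunteers, and LRP6 by -0.29 in volunteer 2 against -0.17 to -0.16 in the others. OR8I2 and B4GAT1 were dim, with mean log2 levels of 4.97 and 6.40 at 0.0 Gy.

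With limma, 0 of 21214 probe sets passed between 0.3 and 0.0 Gy under the settings run, and 498 had an unadjusted p under 0.05. The smallest adjusted p was 1.00 (limma, Benjamini-Hochberg). When adjusted over the list alone, only HBB, a haemoglobin subunit carried by red cells, fell, with a log2 change of -0.60 (limma, adjusted p = 0.0454 over the list). That call was lost with volunteer 1, 2 or 3 left out (highest adjusted p = 0.129, limma) and without the 0.0 Gy array of volunteer 3 (adjusted p = 0.0661, limma), and without the volunteer term (adjusted p = 0.564, limma).

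Camera placed 2 lists above and 5 below the other probe sets at 0.3 Gy with the preset correlation (adjusted p from 6.89e-06 to 0.0476), and 0 with an estimated one. Against no change, 0 of 23 lists passed by fry. The lower ones were platelet markers, eosinophil and basophil markers (-0.10 ± 0.099 SD), red cell markers (-0.10 ± 0.082 SD), NK cell markers (-0.059 ± 0.056 SD) and interferon response genes (-0.042 ± 0.069 SD), and the higher ones small nucleolar RNAs (0.033 ± 0.065 SD) and olfactory receptors (0.037 ± 0.079 SD). For all 7, camera gave adjusted p = 0.736 with an estimated correlation. With any volunteer left out the call held for platelet markers and olfactory receptors. It ended without volunteer 3 for interferon genes (-0.024), NK cell markers (-0.034) and eosinophil and basophil markers (-0.076), without volunteer 2 for red cell markers (-0.083), and without volunteer 1 (0.0071) or 4 (0.023) for small nucleolar RNAs. Interferon genes also lost it without volunteer 1 (-0.034) or 4 (-0.036).

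The slope over all 4 doses called 2 named genes. OSM fell by 0.16 per Gy on the log2 scale (SE 0.025, limma adjusted p = 0.0201) and JUN rose by 0.12 per Gy (SE 0.020, limma adjusted p = 0.0445), each in 4 of 4 volunteers. The mean OSM level was 9.31, 9.21, 9.01 and 8.80 at 0.0, 0.3, 1.5 and 3.0 Gy, and the mean JUN level was 8.10, 8.15, 8.32 and 8.47. The other 5 of the 7 probe sets called, 1 higher and 6 lower in all, had identical values and the same 5 small nucleolar RNA symbols, with a slope of -0.096 per Gy (SE 0.015, limma adjusted p = 0.0201). H2BC21, EGR3, G0S2, PCNA and CD69 had slopes of -0.11, -0.19, -0.18, 0.13 and 0.097 per Gy and an adjusted p of 0.0656 each (limma).

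These calls lay close to the threshold. Over 16 alternatives OSM passed in 6 and JUN in 3, with limma adjusted p from 0.000809 to 1.00 for OSM and from 0.0115 to 1.00 for JUN. The count was 0 without the volunteer term (replicate block), with identical probe sets counted once, without volunteer 1, 2 or 4, and without the 3.0 Gy array of volunteer 1, whose absence moved the OSM slope to -0.13. It was 14 without volunteer 3.

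When adjusted over the list alone, slopes of several list members passed, 12 of the 23 calls with any 1 volunteer left out. PCNA, PLK2 and CDKN1A rose among 50 p53 targets, where 0 passed over all genes. CDKN1A had a slope of 0.061 per Gy (SE 0.017). It also passed among the proposed markers, a list of only 2 measured genes, where it was called with any volunteer left out. JUN, CD69 and MYC rose and EGR3, FOSB and NR4A2 fell among 39 immediate early genes, of which JUN passed over all genes. G0S2, OSM and CXCL8 fell among the NF-kB genes, of which OSM passed over all genes. PPBP, PF4V1 and SPARC rose among the 18 platelet markers, where 0 passed over all genes. PPBP, a chemokine stored in platelet granules, had a slope of 0.11 per Gy (SE 0.024). SNORD81, SNORD30, SNORD28, SNORD115-32 and SNORA38B rose among the small nucleolar RNAs, and H4C16 rose and H2BC21 fell among the histones, with 0 past the threshold over all genes. The small nucleolar RNA list holds only probe sets with 1 symbol. It leaves out the identical small nucleolar RNA probe sets with several symbols, whose called slope was negative. The calls lost without a volunteer included PLK2 (without volunteer 2), MYC (2 or 3), PF4V1 (3 or 4), SPARC (2 or 3), H4C16 (2, 3 or 4) and CDKN1A among the p53 targets (any), besides the 5 small nucleolar RNAs (each without volunteer 2, SNORD81, SNORD30 and SNORD28 also without volunteer 4, and SNORD28 also without volunteer 1). Without the volunteer term, 3 of the 23 passed.

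Of the 23 lists, 12 lay above and 2 below the other probe sets in slope by camera with the preset correlation (adjusted p from 7.15e-12 to 0.0283) and 0 with an estimated one. Against a slope of 0, 0 of 23 lists passed by fry. Platelet markers (0.048 per Gy), B cell markers (0.023 per Gy) and the proposed markers (0.034 per Gy) had camera adjusted p = 0.263 with an estimated correlation. In the exact permutation test of slopes their unadjusted p was 0.0366, 0.0449 and 0.0089, and 0 of 23 lists passed after Benjamini-Hochberg adjustment. Small nucleolar RNAs averaged 0.025 per Gy and heat shock genes 0.014 per Gy (camera, adjusted p = 0.272 and adjusted p = 0.275 with an estimated correlation). P53 targets averaged 0.013 per Gy, red cell markers 0.024 and T cell markers 0.0097 (camera, adjusted p = 0.416, 0.451 and 0.552 with an estimated correlation). NF-kB genes averaged -0.024 per Gy, zinc finger genes 0.0029 and ribosomal proteins 0.0095, each with adjusted p = 0.517 with an estimated correlation by camera. DNA repair genes (0.0044) and histones (0.0037) had camera adjusted p = 0.705, and immediate early genes (-0.017) adjusted p = 0.721 with an estimated correlation. With any volunteer left out, only platelet markers, B cell markers, small nucleolar RNAs and ribosomal proteins kept the call. It ended without volunteer 2 for p53 targets (0.00079), heat shock genes (0.0066), DNA repair genes (-0.0065), T cell markers (-0.0027), zinc finger genes (-0.0043) and histones (-0.00037). Without volunteer 1 it ended for immediate early genes (0.0019), NF-kB genes (-0.0049) and red cell markers (0.0076), and without volunteer 3 for the proposed markers (0.024), red cell markers (0.013) and histones (-0.011). Without volunteer 4 it ended for the proposed markers (0.028), immediate early genes (-0.012), DNA repair genes (0.0029) and zinc finger genes (0.0029).

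Lists without a call in any of these comparisons were oxidative stress and hypoxia, apoptosis regulators, cell cycle and proliferation, and monocyte markers. Their mean log2 changes at 3.0 Gy were -0.032, -0.035, -0.024 and -0.034.

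**Figure D2:**
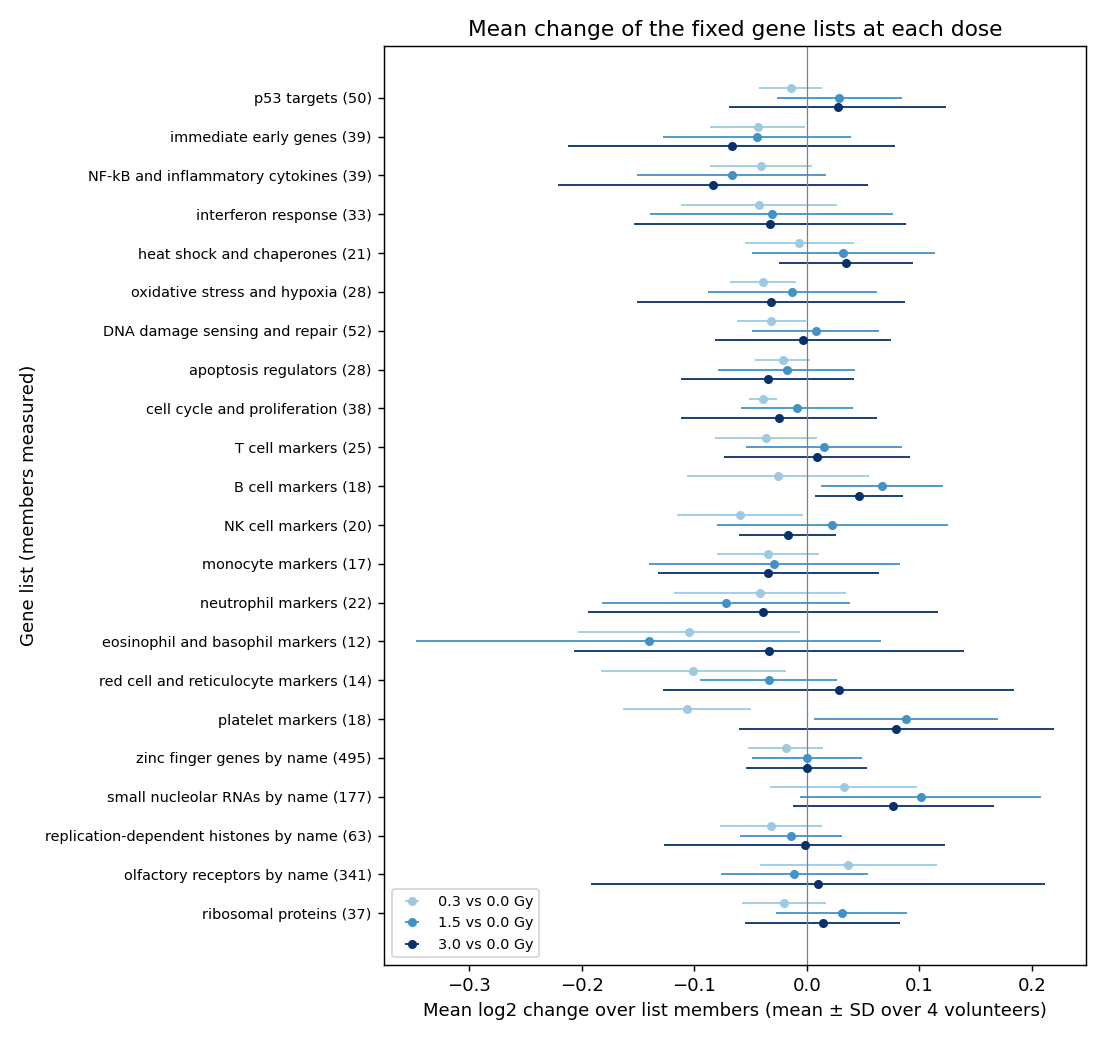
Mean log2 change from 0.0 Gy over the members of 22 gene lists (horizontal axis) at 0.3, 1.5 and 3.0 Gy, with the number of members measured beside each list name (vertical axis). Points are means and bars the SD over 4 volunteers. Platelet markers lie at -0.11 at 0.3 Gy and at 0.088 and 0.080 at the higher doses, and most bars cross 0.

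Compared directly with 0.3 Gy, platelet transcripts had the smallest p-values at both higher doses. GNG11, a G protein subunit gene abundant in platelets and named here after its value was seen, was higher at 3.0 than at 0.3 Gy by 0.49 ± 0.025 SD (limma, adjusted p = 0.0616), in 4 of 4 volunteers. PPBP was higher by 0.39 ± 0.097 SD and SPARC by 0.36 ± 0.21 SD. At 1.5 Gy the differences from 0.3 Gy were 0.35 ± 0.14 SD for GNG11, 0.32 ± 0.065 SD for PPBP and 0.36 ± 0.045 SD for SPARC. With limma, 0 probe sets passed in either comparison, and 924 (3.0 against 0.3 Gy) and 888 (1.5 against 0.3 Gy) had an unadjusted p under 0.05. For 3.0 against 0.3 Gy, GNG11 and PPBP were called without the dimmest 33% of probe sets, and 7 probe sets, these among them, with the robust prior. The rest of the 7 were small nucleolar RNA probe sets with identical values, lower at 3.0 Gy.

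No gene separated 3.0 from 1.5 Gy. SMCR5, FLG2 and DNAJC19 had the smallest p, with log2 differences of 0.25, -0.28 and 0.26. With limma, 0 probe sets passed at these doses under the settings run, 386 had an unadjusted p under 0.05, and the smallest adjusted p was 1.00.

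Changes at different doses were correlated across genes, as they are with no effect when controls are shared. Across 21214 probe sets, which are not independent replicates, the correlation of the changes at 1.5 and 3.0 Gy was r = 0.60, against 0.50 in simulated groups without an effect. The covariance was 0.0034 against a simulated 0.0037. For 0.3 and 1.5 Gy r was 0.37 (simulated 0.50), and for 0.3 and 3.0 Gy 0.41 (simulated 0.50). With the volunteers split so that the changes used different controls, the median r over 6 splits was -0.20 for 1.5 and 3.0 Gy, -0.20 for 0.3 and 1.5 Gy and -0.10 for 0.3 and 3.0 Gy.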

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

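The tests of explanations and the counts of splits in this part were chosen after the results were seen.

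The 7 genes of the immediate early and NF-kB lists that fell at 3.0 Gy when adjusted over the list alone (OSM, EGR3, G0S2, CXCL8, FOSB, NR4A2 and BCL2A1) had a mean log2 change of -0.38 ± 0.22 SD, with -0.71 in volunteer 1 and -0.30 to -0.23 in the others. A lower share of neutrophils would lower neutrophil markers as well. These averaged -0.039 ± 0.16 SD over values of both signs (-0.21, 0.14, 0.038 and -0.12 in volunteers 1 to 4, lowest in volunteer 1 as well). The difference per volunteer was -0.34 ± 0.14 SD, below 0 in 4 of 4 volunteers. Since the 7 genes were picked for their fall on these arrays, an excess over unpicked markers was built in. The difference therefore cannot weigh against a lower share. The markers alone showed no fall beyond their spread. If chance values at 3.0 and 0.0 Gy had picked these genes, no difference would be expected between the 0.3 and 1.5 Gy arrays. Those arrays entered the error used in the picking but not the log2 change. From 0.3 to 1.5 Gy the mean difference was -0.16 ± 0.048 SD, again below 0 in 4 of 4 volunteers. The picking favoured genes with a small error, so this spread may be too small. OSM, CXCL8 and BCL2A1 had also been seen below control at 1.5 Gy before this test was chosen. Chance is therefore not excluded. A lower level of these 7 genes after irradiation is a hypothesis not tested further, and it covers these 7 genes alone, since in the immediate early list JUN and CD69 rose at 3.0 Gy when adjusted over the list alone. A lower share of neutrophils stays open. So do the order in which tubes were handled and a change in another cell type, which were not tested.

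PCNA, PLK2, JUN and CD69 had a mean log2 change of 0.36 ± 0.10 SD at 3.0 Gy. A higher share of T and B cells would raise their markers as well. These averaged 0.025 ± 0.044 SD, and the difference per volunteer was 0.33 ± 0.064 SD. Since the genes were picked for their rise on these arrays, an excess over unpicked markers was built in. The difference therefore cannot weigh against a higher share. The pooled T and B cell markers showed no rise beyond their spread. On their own, B cell markers averaged 0.046 ± 0.039 SD and T cell markers 0.0092 ± 0.082 SD, each above 0 in 3 of 4 volunteers. The slope of the B cell markers was 0.023 ± 0.0075 SD per Gy, above 0 in 4 of 4 volunteers. That of the T cell markers was 0.0097 ± 0.028 SD per Gy, above 0 in 2 of 4. The 0.3 and 1.5 Gy arrays entered the error used in the picking but not the log2 change. From 0.3 to 1.5 Gy the mean difference was 0.24 ± 0.060 SD, above 0 in 4 of 4 volunteers. Here too the spread may be too small, and PCNA and CD69 had already been seen above control at 1.5 Gy. Chance in the log2 changes that picked these genes is therefore not excluded. An early response of these stress and activation genes to dose is a hypothesis, found and tested on the same volunteers. A higher share of T and B cells and handling order stay open here too.

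Platelet markers stood at -0.11 ± 0.057 SD at 0.3 Gy and were higher at 1.5 than at 0.3 Gy by 0.19 ± 0.047 SD and at 3.0 than at 0.3 Gy by 0.19 ± 0.14 SD, with 17 of 18 markers higher each time. A candidate explanation is platelet carry-over that differed between tubes, since leukocytes were collected by centrifugation after red cell lysis. With dose and volunteer removed, the markers still varied together, with a mean pairwise correlation of 0.370 against a median of 0.061 and a 95th percentile of 0.180 in 1000 random lists matched on mean expression. Markers of monocytes (0.511), neutrophils (0.498) and eosinophils and basophils (0.444) varied together more strongly, so this is not particular to carry-over. Carry-over and an effect of dose on platelets themselves both stay open.

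The 7 probe sets called by slope were reached by 1 of 100 assignments of doses within volunteers, the real one, and the highest of the others was 1, but 5 of the 7 have identical values, and with identical probe sets counted once 0 were called. Slopes with an unadjusted p under 0.05 numbered 1163, and 33 of the 100 assignments gave as many, with a highest other count of 3920. Chance is therefore not excluded for the slopes as a whole. The 14 lists called by slope were reached by 6 of 100, with a median of 8 and a highest other count of 17, so chance is not excluded for them either. For the pairwise comparisons, where 0 probe sets were called, counts at an unadjusted p under 0.05 were compared over the 8 splits that part every volunteer's pair, too few for a share under 0.05. The real counts and highest others were 498 and 773 (0.3 against 0.0 Gy, 5 splits with as many, the real one included), 591 and 4146 (1.5 against 0.0 Gy, 6 splits), 772 and 4931 (3.0 against 0.0 Gy, 7 splits), 888 and 709 (1.5 against 0.3 Gy, 1 split), 924 and 1543 (3.0 against 0.3 Gy, 3 splits), and 386 and 1500 (3.0 against 1.5 Gy, 8 splits). Lists called by camera with its preset correlation numbered 7, 9 and 9 at 0.3, 1.5 and 3.0 Gy. The other splits of the pairs gave up to 10, 15 and 18, so chance is not excluded for these list calls either. The splits with 4146 and 4931 exchange the 2 arrays of volunteer 3, which points to a structure of the samples. The leading residual component, with 30.7% of the variance after dose and volunteer are removed, had its extremes on the 0.0 Gy array of volunteer 3 (-13.4) and the 3.0 Gy array of volunteer 1 (14.4).

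In 7 of 180 groups of 4 values tested, 1 volunteer or array lay far from the others, where chance gives about 9. At 3.0 Gy these were OSM in volunteer 1 (-0.99), PLK2 in volunteer 2 (0.77), and in volunteer 3 the NK receptor gene KLRC3 (-0.20, others 0.29 to 0.35) and the eosinophil protease gene PRSS33 (0.30, others -0.24 to -0.18). The others were LRP6 at 0.3 Gy in volunteer 2 (-0.29), the p53 target mean at 1.5 Gy in volunteer 2 (0.11, others -0.0019 to 0.0028), and the 3.0 Gy array of volunteer 1, whose mean correlation with the other arrays was 0.9898.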

How the results depend on the processing

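Identical probe sets counted once, the platelet covariate and the single arrays left out were chosen after seeing the data. Where no value shows otherwise, the cause was not tested. In the fit without the replicate block, 0 probe sets had a called slope (7 with it), and lists called at 0.3 Gy went from 7 to 4. Slope calls were also 0 with volunteers as a random effect, median centring, all probe sets, identical ones counted once (5 of the 7 repeat each other) and the platelet covariate, 12 without the dimmest 33%, 16 with the robust prior and 3 with dose rank. They ranged from 0 to 14 with a volunteer or an array left out. At 3.0 against 0.0 Gy the robust prior called 14. At 3.0 against 0.3 Gy it called 7, and leaving out the dimmest 33% called 2. The 5 probe sets that repeat each other are counted in these 7 and in the 14 at 3.0 against 0.0 Gy. They are also counted in the 12, 14 and 16 slope calls. At 1.5 against 0.0 Gy leaving out volunteers or arrays gave 0 to 1. Lists called at 0.3 Gy (7) numbered 3 without the dimmest 33%, 11 with all probe sets tested, 12 with the robust prior, 11 with all probe sets of members, 0 with the platelet covariate and 5 to 11 with a volunteer or array left out. The platelet covariate left 5 of 9 lists at 3.0 Gy and 4 of 14 for the slope. The estimated correlation left 0 lists at 0.3, 1.5 and 3.0 Gy and for the slope. Some list means changed side relative to other probe sets. With the platelet covariate they were -0.0077 (small nucleolar RNAs) and -0.0037 (olfactory receptors) at 0.3 Gy, -0.069 (histones) at 1.5 Gy and -0.022 (ribosomal proteins) at 3.0 Gy, with slopes of -0.0082 (T cell markers), -0.015 (histones) and -0.0075 (ribosomal proteins). With a volunteer or array left out they ranged from -0.076 to -0.024 (interferon genes, 0.3 Gy), -0.11 to -0.0058 (immediate early genes, 3.0 Gy) and -0.083 to 0.062 (olfactory receptors, 3.0 Gy). The slopes ranged from -0.029 to 0.0019 (immediate early genes), -0.018 to 0.012 (oxidative stress), -0.0065 to 0.014 (DNA repair) and -0.032 to 0.011 (olfactory receptors). Of 3233 gene values under alternatives, 3190 kept their side of the threshold, 20 passed newly and 23 lost their call. The 23 were all slopes of OSM or JUN, the only gene values called in the main fit. These passed in 6 (OSM) and 3 (JUN) of 16 alternatives, so the values that kept their side were mostly uncalled both times. Of 1564 list values, 1358 kept theirs, 87 passed newly, 102 lost their call and 17 changed side. Among those that kept it, 46 gene and 115 list values, uncalled both times, changed sign. How far signal stands above background was not analysed here, so dim genes are the least certain.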

Other observations

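Among the B cell markers, the signalling adaptor genes BANK1 and STAP1 had log2 changes of 0.20 ± 0.20 SD and 0.22 ± 0.24 SD at 3.0 Gy, each above 0 in 3 of 4 volunteers, and MS4A1, which encodes the surface protein CD20, one of 0.13 ± 0.15 SD. The chaperone gene HSP90AB1 had a log2 change of 0.13 ± 0.065 SD at 3.0 Gy, above 0 in 4 of 4 volunteers, and HSPD1, a mitochondrial chaperone gene, one of 0.19 ± 0.34 SD, above 0 in 2 of 4. Of the other heat shock genes named, HSP90B1 averaged 11.78 at 3.0 Gy against 11.70 at 0.0 Gy. HSPB1 went the other way, with 9.36 against 9.51. MIR17HG stood at 0.35 ± 0.26 SD at 3.0 Gy, above 0 in 4 of 4 volunteers. None of these passed over all genes, and the list members among them did not pass when adjusted over the list alone (n = 4 volunteers).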
